A study of Homo sapiens with 3 samples.

How the data were processed

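RNA was measured in 3 libraries of NCI-H209, an established human small cell lung cancer line that grows with neuroendocrine features. Per the labels, the cells carried a doxycycline-inducible lentiviral short hairpin RNA, either 1 of 2 hairpins against YES1, named sh490 and sh1362, or a control hairpin against GFP, a gene absent from human cells. Doxycycline was given at 1 µg/mL every 2 days, and there was 1 library per hairpin. Polyadenylated RNA was extracted with Trizol and columns and made into libraries with a SMARTer mRNA kit, per the labels' protocols. The time from induction to harvest and the sequences of the hairpins are not given in the sources used here.

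The deposited values are raw read counts per gene, 1 table per library, with no normalization. Reads were aligned with STAR 2.6.1c to GRCh38 after quality checks with FastQC 0.11.8, per the submitters' processing notes. Genes were counted with featureCounts 1.6.0 on exons of GENCODE version 32, per the file headers. The recorded command set no option for strand or read pairs, so the program's defaults applied: reads from both strands were added together, and reads aligning to several places or overlapping several genes were left out. Reads of overlapping and antisense genes therefore cannot be told apart by strand. Near-identical copies such as HBA1 and HBA2, AMY2B and its relatives, and the HLA genes may have lost reads, so their levels are uncertain. Each table lists 60609 genes, of which 60295 were matched to a symbol and 58502 to the GENCODE version 29 annotation, the reference used here for biotypes and untranslated regions. Gene coordinates are those of the tables (GRCh38). In 27622 genes at least 1 read was counted.

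Total counts were 7791747 for sh490, 7421552 for sh1362 and 4899006 for shGFP. Where no read is seen, 3 counts are the upper limit that a count of 0 allows, equal to 0.385, 0.404 and 0.612 CPM (counts scaled to the library total) in these libraries. Intervals given for single libraries are exact 95% intervals of counts; reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

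The main test compared both YES1 hairpins, taken as 2 samples of 1 group, with shGFP by edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr with its defaults, the robust quasi-likelihood F test, two-sided, and Benjamini-Hochberg adjusted p under 0.05. It kept 15708 genes. Only the hairpins share a group, so the spread came from 1 residual degree of freedom moderated across genes, and the lone shGFP library was assumed to vary like them. The labels do not say that the hairpin libraries came from separate cultures, so p-values measure only the spread between these libraries, in which hairpin-specific effects are included. Each hairpin was also set against shGFP by size alone, without a test, as log2 CPM with a prior count of 2 in the 11638 genes with a mean of 5 CPM or more. A gene was counted when it lay at least 2-fold apart.

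Both fold changes share the shGFP library, so 100 sets of 3 unchanged libraries were simulated from the real means, depths and edgeR dispersions, and the same counts and correlations were taken from them; 100 further sets were used for the lists, ranked the same way among fewer random lists. For 36 gene lists with 895 entries, covering kinases, lineage, immune, growth, stress, metabolic and other-cell-type genes, the median log2 fold of the measured members was ranked as a percentile among 10000 random lists of equal size matched on mean expression in 20 bins. A list was said to stand apart when its percentile was under 2.5 with both hairpins or above 97.5 with both. That rank describes these libraries and is no test across samples. Co-regulated members move together, so lists of real pathways leave the random range more easily than random lists do.

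Named genes followed 1 rule: protein-coding genes with a mean of 5 CPM or more, the 12 higher and 12 lower with both hairpins by the smaller of their absolute folds with genes past the test first, the 6 most different each way between hairpins, the Src-family list, and up to 4 members per list. The groups, tests, lists, naming rule and most other settings tried were fixed before the data were examined. The ranking of lists between the hairpins, the choice of S100A9, the blood gene sums without ALAS2 or CORO1A, the simulated lists, the lists with another library as reference and the comparison of word positions in YES1 were made after values had been seen. Fits with each library in turn as the lone one were run; they called 0 genes for sh490, 262 for sh1362 and 4 for shGFP, counts that follow from the spread of the libraries and support nothing further. The genes of the fit with sh1362 alone were also inspected, and they are not reported because that split was picked by its outcome. Some genes that the naming rule takes are not reported here.

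To look for off-target silencing, words of 7 bases in the longest annotated 3' untranslated region of 10884 genes were related to each library's difference from the mean of the others by linear regression with the region's length and GC content as covariates, for 16180 words present in at least 50 genes. The largest of 100 permutations gave the range without a relation. Trends with GC content and gene length were removed with lowess (statsmodels 0.14.6). DESeq2 1.42.0, limma-voom from limma 3.58.1, other scaling, filters, prior counts and thresholds were run as alternatives.

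The edgeR step was tested on simulated counts of these 3 libraries with 200 changed genes per fold size. It recovered 4.5% of genes changed 2-fold, 81% at 4-fold, 94% at 8-fold, 98.5% at 16-fold and 99% at 32-fold. There were 7, 15, 3, 9 and 21 false calls among 15187, 15230, 15199, 15298 and 15263 genes, beside 9, 162, 188, 197 and 198 recovered ones. The share of false calls among all calls therefore exceeded the nominal 0.05 at 2-fold, 4-fold and 32-fold. With the folds of sh490, 0 of 50 random lists fell outside the range, and 50 of 50 lists shifted by -0.3 fell below it. The rule that asks for both hairpins was not tested in this way. A planted word that lowered its genes by 0.1 log2 units ranked first in 20 of 20 trials, and at 0.05 in 8 of 20, over 10884 genes.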

Results

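Gene expression was measured by RNA sequencing in NCI-H209 cells in which YES1, a Src-family tyrosine kinase, was targeted by inducible hairpins. The series title places the work in a study of dasatinib, an inhibitor of Src-family and ABL kinases, in small cell lung cancer. The libraries were sh490 and sh1362, each carrying a different hairpin against YES1, and shGFP, the control. There was 1 library of each, so differences of a single hairpin from shGFP have no replicate check. Reads were detected for 22954 genes in sh490, 23097 in sh1362 and 21403 in shGFP, the shallowest library. Transcripts of the mitochondrial genome took 5.50%, 7.78% and 5.47% of the counts.

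YES1 was far lower with both hairpins than in the control. YES1 (ENSG00000176105.14, chromosome 18, 721588 to 812546 on the minus strand of GRCh38) had 163 counts in sh490, 216 in sh1362 and 1465 in shGFP. These equal 20.6, 29.3 and 303.7 CPM. The normalised level was 6.79% of shGFP with sh490 (exact 95% counting interval 5.74 to 7.98) and 9.66% with sh1362 (8.33 to 11.1). In the edgeR quasi-likelihood test the log2 fold was -3.60 with a standard error of 0.30, and the Benjamini-Hochberg adjusted p was 0.00761, with YES1 lower in 2 of 2 hairpin libraries. Among genes with a mean of 5 CPM or more only, that adjusted p was 0.0506, above 0.05, so the call for YES1 depends on the filter.

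YES1 was the only tested member of the Src-family list to pass that test, adjusted over all genes and also adjusted over the list alone. FRK, a related kinase, was lower with log2 folds of -0.69 and -1.01 and did not pass (edgeR adjusted p 0.986). LYN had log2 folds of -0.39 and -0.65, LCK -0.38 and -0.63, and SRC -0.26 and -0.19, none past the test. LCK was not searched for 7-base words in its 3' untranslated region. FRK and LYN carried a 7-base 3' untranslated word that went with lower values in sh490. Such words are common: of 10884 genes searched, 24.1% carried one linked to sh490 and 23.1% one linked to sh1362. They were also chosen from these same libraries, so carrying a word does not show that a gene was silenced off target. Of the 10 list members, 8 were tested; 5 lay lower with both hairpins, 2 higher with both and 1 opposite. The list's median log2 fold was -0.32 with sh490 and -0.43 with sh1362 (percentiles 1.91 and 3.30 of random lists), so it did not stand apart with both. These medians include YES1 itself. Without genes carrying a word of either hairpin, YES1 among them, the percentiles were 41.2 and 20.9.

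**Figure D1:**
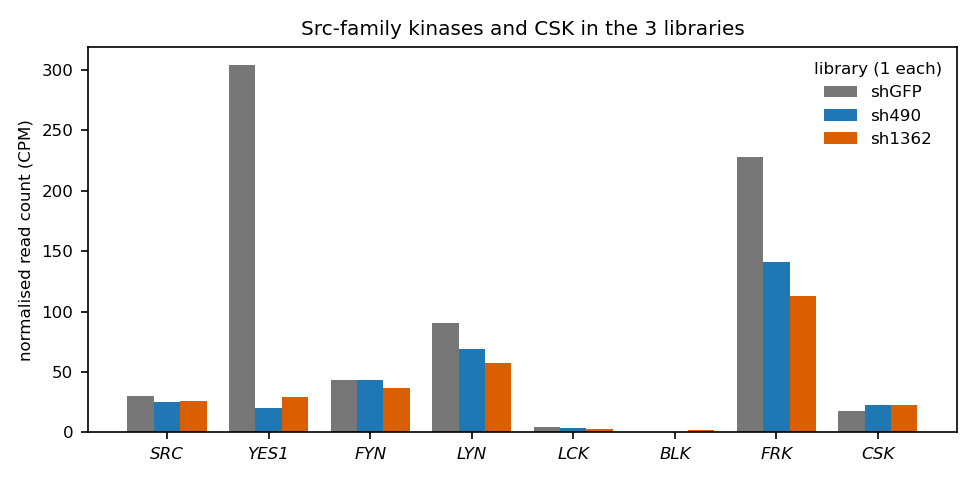
Normalised read counts (CPM, vertical axis) of the tested Src-family kinases and of CSK, the kinase that restrains them, with 1 bar per library and no error bars because each hairpin has 1 library. YES1 stood at 303.7 CPM in shGFP against 20.6 in sh490 and 29.3 in sh1362.

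To find which transcripts differed when YES1 was silenced, both hairpin libraries were compared with shGFP. Besides YES1, the transcripts past the test were the adult globins, the oxygen carriers of red blood cells, far higher in shGFP than with both hairpins. Blood RNA in the shGFP library is a candidate explanation, taken up below. HBB had 136 counts in sh490, 140 in sh1362 and 3124 in shGFP, 2.66% (2.22 to 3.15) and 2.94% (2.46 to 3.48) of the control level. HBA1 had 4, 1 and 208 counts, and HBA2 had 7, 9 and 208. Of 15 other red cell genes 37.2% of the counts lay in shGFP (26.5 to 48.9), against its 24.4% of all counts, and 25.4% (15.3 to 37.9) without ALAS2. Of 15 white cell genes the share was 36.1% (31.1 to 41.3), and 78.3% (65.8 to 87.9) without CORO1A, with 3 counts in sh490, 10 in sh1362 and 47 in shGFP. Both of these genes were left out only after the values had been seen. S100A9, an abundant transcript of neutrophils that was picked after its values were seen, had 1, 0 and 20 counts and passed only without a filter on low counts (edgeR adjusted p 0.0101). No gene rose past the test.

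By edgeR's quasi-likelihood test, 0 of 15708 genes were higher and 4 lower at a Benjamini-Hochberg adjusted p under 0.05: HBB (adjusted p 0.000869), HBA1, HBA2 and YES1. At an unadjusted p under 0.05 there were 357 higher and 327 lower genes, 684 in all, where 785.4 would pass by chance. DESeq2 called 1 gene higher (ITPK1) and 4 lower, limma-voom 0 and 2, and edgeR without a filter on low counts 22 and 36. All 58 of these had been tested in the main fit; without the filter the median prior degrees of freedom were infinite, so that most genes shared a fitted spread, against 7.16 in the main fit. In simulated data with 200 changed genes, 81% of 4-fold but 4.5% of 2-fold changes were recovered. A change near 2-fold was therefore mostly not detectable with these libraries. The adjustment is stricter where fewer genes change, so the 81% need not hold for the real data. ITPK1, at 10.5-fold with sh490 and 9.03-fold with sh1362, did not pass (edgeR adjusted p 0.519).

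The genes that lay farthest from the control in the same direction with both hairpins did not pass the edgeR test, apart from YES1 and the globins. Their calls depend on the filter: without it 11 more passed, namely INHBA, ITPK1, TRPA1, ABCA1, GDA, GEM, CCDC154, EGFL6, CEACAM5, ABTB3 and COL11A1. ITPK1, an inositol phosphate kinase, had 160 and 128 counts against 8 in shGFP, log2 folds of 3.39 and 3.18 (edgeR adjusted p 0.519, DESeq2 adjusted p 0.0328). CCDC154 was higher by log2 1.81 and 2.11, and CEACAM5, a cell-surface adhesion glycoprotein, by 2.43 and 1.56. ATOH8, a basic helix-loop-helix transcription factor, was higher by 1.86 and 1.76, and COL11A1, a fibrillar collagen, by 1.55 and 2.36. ABTB3, RAB40B, AMY2B, FAM241A, G0S2, KLHL26 and IL17RC completed the 12 highest. On the other side, INHBA, which encodes the activin A subunit, had log2 folds of -2.98 and -2.03, and EGFL6 -2.64 and -1.88. TRPA1, a cation channel that senses irritants, had 189 and 177 counts against 410, log2 folds of -1.82 and -1.81. The lipid exporter ABCA1 had -1.61 and -2.57, the guanine deaminase GDA -1.57 and -3.05, and the GTP-binding protein GEM -1.85 and -2.26. MAFF, a small basic leucine zipper factor, had -1.66 and -1.96, and NIPSNAP3B -1.54 and -1.58. The 3' untranslated regions of INHBA, ABCA1 and GDA carried a 7-base word that went with lower values in sh1362, and those of INHBA, GDA and TRPA1 a word that did so in sh490. FAM241A, on the higher side, carried a word linked to sh1362. CCDC154, AMY2B and IL17RC, also on the higher side, were not searched for words. Among genes at least 2-fold lower with sh1362, 43.4% carried a word of that hairpin, against 17.0% of those at least 2-fold higher. With sh490 these shares were 42.6% and 12.3%. The words were picked from the same values, so these shares are no independent support.

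By size alone, 94 genes were at least 2-fold higher and 69 at least 2-fold lower with both hairpins, among 11638 genes. With sh490 alone 162 were higher and 165 lower, and with sh1362 alone 384 and 698. Independent lists of these sizes would share 5.35 higher and 9.90 lower genes. Simulated unchanged libraries that share a control gave 100.5 higher (range 78 to 131) and 49 lower (32 to 77) with both. Their spread was estimated from the hairpins themselves, so it includes effects of single hairpins. These simulated libraries did not match the single hairpins, giving 310 higher (265 to 362) and 291 lower (243 to 335) for sh490, and 308.5 (258 to 370) and 295 (256 to 349) for sh1362. Sets simulated with counting error alone, which leave out any other spread between libraries, gave 0 higher (0 to 4) and 0 lower (0 to 1) with both. Across genes, which are not independent replicates, the folds of the hairpins had a Pearson r of 0.555 (simulated 0.515, 0.499 to 0.531) and a Spearman rho of 0.516 (0.472 to 0.507 simulated). Their covariance was 0.1405 against 0.1333 simulated, a difference of 0.00720. The control could not be split, and part of any excess may come from it.

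**Figure D2:**
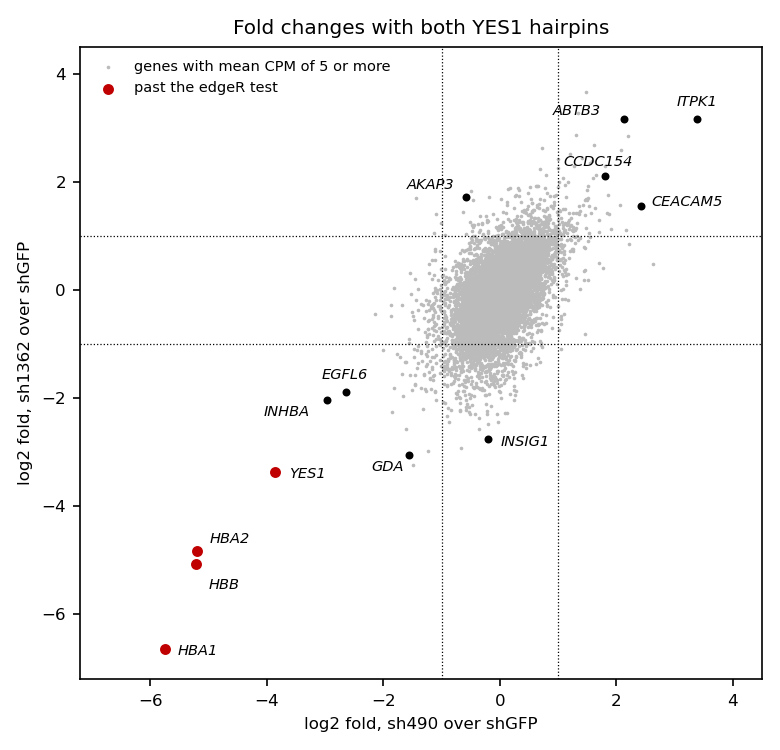
Each point is a gene with a mean of 5 CPM or more, placed by its log2 fold over shGFP with sh490 (horizontal) and with sh1362 (vertical), and dotted lines mark 2-fold. YES1 and the 3 globin genes, in red, passed the edgeR test, and the black points mark other genes named by the fixed rule, such as ITPK1 at 3.39 and 3.18 and INSIG1 at -0.20 and -2.76.

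Among the 36 lists, 4 stood lower with both hairpins and 0 higher. They held genes of DNA replication, DNA repair, the MAPK response and YAP/TEAD transcription. Simulated unchanged libraries gave 0 lower (range 0 to 1), but their genes are independent, and members of a pathway move together. With sh490 as the shared reference in place of shGFP 2 lists stood apart from it with both other libraries, and with sh1362 8 did, so the count of 4 does not set shGFP apart from the other libraries as a reference. No member of the 4 passed the edgeR test, adjusted over all genes or adjusted over the list alone, but without a filter on low counts EXO1 (edgeR adjusted p 0.00146) and CHEK1 (0.00256) did. In the same comparison the shGFP library carried the globin transcripts given above, and the leukocyte marker list summed to 6.53 CPM in shGFP against 4.24 in sh490 and 5.39 in sh1362, while its medians were 0.42 and 0.10, with 2 of 3 measured members higher with both hairpins.

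Of the 40 S phase and replication genes, 32 were lower with both hairpins (14 in simulated unchanged libraries, 5 to 20), 0 higher with both and 8 opposite. Their median log2 fold was -0.29 with sh490 and -0.96 with sh1362, each below all 10000 random lists. CDC6, which loads the replicative helicase, had -0.79 and -1.36, MCM10 -0.75 and -1.57, and E2F8, a cell-cycle transcription factor, -0.68 and -2.22. Of 33 DNA damage response genes 26 were lower with both (simulated 11, 5 to 16), with medians of -0.28 and -0.84 (percentiles 0 and 0). The checkpoint kinase CHEK1 had -0.97 and -2.07, and the exonuclease EXO1 -1.18 and -1.82. CHEK1 carried a word linked to sh1362 and CDC6 a word linked to sh490. Both lists also differed between the hairpins, lower with sh1362, by median log2 differences of 0.66 (percentile 100) and 0.43 (99.99).

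For MAPK and immediate early genes, 16 of 27 were lower with both hairpins (simulated 9, 3 to 14) and 4 higher. The medians were -0.41 and -0.62, below all random lists. DUSP5 and DUSP6, phosphatases induced by ERK signalling, had log2 folds of -1.13 and -1.23, and of -0.76 and -1.47. The feedback inhibitors SPRY4 and SPRY1 had -0.75 and -1.15, and -0.64 and -1.24. DUSP6 carried words linked to both hairpins and SPRY1 a word linked to sh490. In the YAP/TEAD target list, 10 of 19 genes were lower with both (simulated 6, 2 to 12), 4 higher and 5 opposite, and the medians were -0.37 and -0.62 (percentiles 0.03 and 0.02). IGFBP3, an IGF-binding protein, had -0.86 and -1.17, F3, which encodes tissue factor, -0.97 and -0.96, and PTPN14 -0.72 and -1.64; F3 carried a word linked to sh490 and PTPN14 one linked to sh1362. This list no longer stood apart when the mean replaced the median (percentiles 2.36 and 3.30), nor without genes carrying a 3' untranslated word linked to either hairpin (4.96 and 68.9). Of its 16 searched members 9 carried such a word, so this left out much of the list. The words had also been chosen from these same libraries.

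Immune lists did not stand apart with both hairpins. The chemokine and cytokine list had medians of -0.84 and -0.54 (percentiles 0 and 2.5), with CXCL8, a neutrophil attractant, at -1.12 and -1.89 and CXCL1 at -1.25 and -1.04. CXCL8 passed adjusted over the list alone (edgeR adjusted p 0.0296) but not over the NF-kB list, where it also stands (0.0559), nor over all genes, except without a filter on low counts (0.000764). NF-kB targets had medians of -0.11 and -0.67 (percentiles 17.0 and 0.03), with TNFAIP3, an inhibitor of that pathway, at -1.21 and -1.52. Interferon response genes had medians of 0.34 and 0.12 (percentiles 99.9 and 80.2), with OAS1 at 1.15 and 1.06. MHC class I genes had medians of 0.00 and -0.13 (55.2 and 15.6), MHC class II genes -0.11 and -0.68 (26.8 and 1.20), and immune checkpoints and ligands -0.05 and -0.06 (29.8 and 34.3). Genes sensing nucleic acid in the cytosol had 0.07 and 0.29 (70.7 and 93.8).

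With sh490, 13 of 36 lists fell outside the central 95% of random lists, and with sh1362 11, where 1.8 would by chance for independent genes. These ranks describe single libraries with a shared control.

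**Figure D3:**
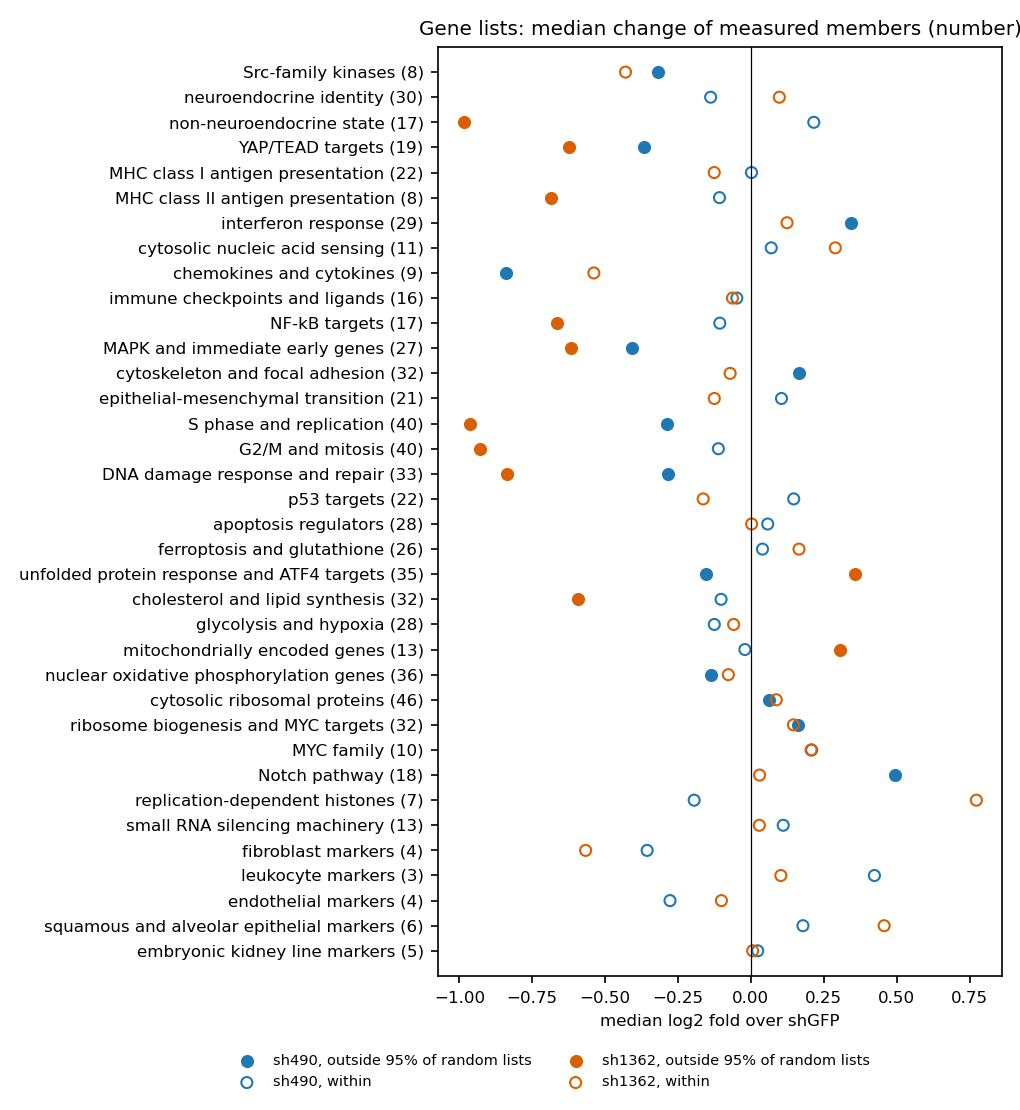
Median log2 fold over shGFP (horizontal axis) of the measured members of each list with sh490 (blue) and sh1362 (orange), with the number of members in brackets. Filled points lie outside the central 95% of random lists, and S phase and replication genes had medians of -0.29 and -0.96.

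The hairpins were then compared with each other, since both target YES1. The sterol sensor INSIG1, which restrains cholesterol synthesis, had 1060 counts in sh490, 165 in sh1362 and 741 in shGFP. VCAN, an extracellular matrix proteoglycan, had 153, 25 and 95, and ERBB4, a receptor tyrosine kinase, 89, 14 and 50. CHRNA9, C8orf33 and FOXI3 were also far higher with sh490 than with sh1362, at log2 differences of 2.36, 2.27 and 2.27. In the other direction AGR2, an endoplasmic reticulum protein of secretory epithelia, had 40 counts in sh490, 222 in sh1362 and 54 in shGFP. RORB, AKAP3, DSG1, ADRB1 and PPP1R3C were higher with sh1362 as well, at log2 differences of -2.33, -2.31, -2.26, -2.17 and -2.13 for sh490 over sh1362.

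In all, 687 of 11638 genes lay at least 2-fold apart between the hairpins, 452 higher with sh490 and 235 higher with sh1362. Simulated unchanged libraries, whose spread was estimated from these same hairpins, gave 287 (249 to 326) and 283.5 (247 to 317). With 1 library per hairpin these differences compare libraries, and no test was made. INSIG1, VCAN, ERBB4, C8orf33 and RORB carried a 3' untranslated word that went with lower values in sh1362, and ERBB4 and DSG1 one that did so in sh490. RORB was nevertheless higher with sh1362, against its word, and ERBB4 higher with sh490, against its sh490 word. Of all genes searched, 23.1% carried a word linked to sh1362 and 24.1% one linked to sh490.

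Mitotic genes were among the groups that differed between the hairpins. Of 40 G2/M genes 15 were at least 2-fold lower than shGFP with sh1362 and 0 with sh490, and the list's medians were -0.93 and -0.11. CDK1 had log2 folds of -0.62 with sh490 and -1.20 with sh1362, and CCNA2, which encodes cyclin A2, -0.34 and -1.40. Cholesterol and lipid synthesis genes had medians of -0.10 and -0.59 (-0.37 with sh1362 over the 22 members without its words), with MSMO1, an enzyme of sterol synthesis, at -0.81 and -1.01. Unfolded protein response and ATF4 targets had medians of -0.15 and 0.36, with SLC6A9 at 1.25 and 1.43 and ASNS, which makes asparagine, at -0.93 and -0.79, and 14 of 35 members lay opposite. The non-neuroendocrine list had medians of 0.22 and -0.98, with YAP1 at -0.67 and -2.92 and EPHA2 at -1.28 and -2.46, though 9 of its 17 members lay opposite and 3 were at least 2-fold higher with sh490. CDK1, CCNA2 and YAP1 carried a word linked to sh490, and EPHA2 was not searched for words. The members named for these lists were taken by the size of folds shared by both hairpins. They therefore need not show the difference between hairpins, and ASNS lay against its list's median with sh1362. The mitochondrially encoded genes had medians of -0.02 and 0.31, beside the 7.78% of counts that mitochondrial transcripts took in sh1362. Between the hairpins 12 lists lay outside the central 95% of random lists, 9 higher with sh490 and 3 with sh1362, by a ranking chosen after the values were seen.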

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

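The alternatives without globins and without word-carrying genes, and the test of YES1 with robust estimation off or among genes of 5 CPM or more, were added after seeing the data. The log2 fold of YES1 stayed between -3.86 and -3.36, but its adjusted p was 0.0506 (log2 fold -3.596) among genes with a mean of 5 CPM or more, where YES1 was the 1 of the 4 calls that was lost. In the other alternatives with a test it stayed below 0.05, from 0.0304 (without the globins) to 1.17e-29 (edgeR, no filter). Without a filter on low counts edgeR called 22 genes higher and 36 lower, with an infinite median of prior degrees of freedom against 7.16. DESeq2's test called 1 higher. Limma-voom called 2 lower (HBB and YES1), with adjusted p of 0.455 for HBA1 and 0.147 for HBA2, and without the 3 globin genes 1 was lower, since the others had been removed. Leaving out a hairpin leaves no residual degrees of freedom for edgeR, so these counts have no such value. Counts by size moved with their own thresholds. At a mean of 1 CPM, 368 genes were higher with both hairpins, 210 lower and 1599 apart between them, and at 20 CPM 27, 23 and 327. At 1.5-fold there were 446, 390 and 2371, and at 3-fold 11, 10 and 122. With 1 hairpin left out the other alone gave 162 to 384 higher and 165 to 698 lower, so the balance turned from more higher genes to more lower ones. Without genes carrying a word of either hairpin 43 were lower with both and 357 apart between them, partly because fewer genes were counted. The correlation of the folds was 0.532 at 20 CPM. Lists standing apart with both hairpins numbered 4 to 6 under the alternatives. The chemokine list joined them with DESeq2's size factors (percentiles 0 and 2.45), NF-kB targets (0.25 and 0.03) and G2/M genes (1.14 and 0) with members of 5 CPM or more, and ribosomal proteins with the mean (99.98 and 99.67, higher). Without word-carrying genes YAP/TEAD targets no longer stood apart, while chemokines (0.01 and 0.70) and NF-kB targets (0.21 and 0.11) did. No list standing apart turned its direction, nor did the 24 genes named for both hairpins or the difference of the 12 named between them. The fold of ADRB1 over shGFP turned from 0.349 to -0.102 with limma-voom, and that of VCAN with sh490 from -0.025 to 0.018 with total counts. In all, 9 lists that did not stand apart changed sign in 16 cases of the mean of both medians, such as leukocyte markers (0.263 to -0.317 with the mean), epithelial-mesenchymal genes (-0.0101 to 0.0501 at 5 CPM) and p53 targets (-0.00834 to 0.117 at 5 CPM). With sh490, the median of MHC class I genes went from 0.0022 to -0.0055 with DESeq2's size factors and that of mitochondrially encoded genes from -0.0205 to 0.0228 with total counts. Scaling by total counts moved the median of all genes to 0.04 with sh490. Depth limits the shGFP library most, where 1 read equals 0.204 CPM. No paired analysis was possible because the groups share fewer than 2 replicate numbers, which only follow accession order.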

Other observations

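Tests of the shared control, of the hairpin numbers and of sums without a leading gene were chosen only after results had been seen. Neuroendocrine identity genes lay on both sides of the control. INSM1, a zinc-finger factor of neuroendocrine cells, was higher with both hairpins, at log2 folds of 0.86 and 1.75, and UCHL1 at 0.65 and 0.71, while ENO2 stood at -0.52 and -1.28, none past the edgeR test. Adjusted over all genes, INSM1, LFNG and GADD45A passed the edgeR test only without a filter on low counts (adjusted p 0.00699, 0.00202 and 0.000979). The neuroendocrine list had medians of -0.14 and 0.10 (percentiles 3.25 and 87.7), with 9 members higher with both, 10 lower and 11 opposite.

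Notch pathway genes had medians of 0.50 and 0.03 (percentiles 99.99 and 55.5). LFNG, which glycosylates Notch receptors, stood at log2 folds of 1.85 and 1.43 and passed edgeR's test adjusted over the list alone (adjusted p 0.0222), not over all genes. In the p53 list GADD45A, a stress-response gene, stood at -1.42 and -1.45 (edgeR adjusted p 0.00962 over the list alone, 0.858 over all genes), against TP53I3 at 0.96 and 1.12, and the medians were 0.15 and -0.16 (percentiles 92.3 and 11.6). Ribosome biogenesis and MYC targets had medians of 0.16 and 0.15 (99.8 and 96.6), ribosomal proteins 0.06 and 0.09 (98.8 and 95.1) and the MYC family 0.21 and 0.21 (96.7 and 91.6), with MYC at 0.49 and 0.77. Apoptosis regulators had 0.06 and 0.00, with CASP9 at 1.14 and 1.22. Ferroptosis genes had 0.04 and 0.17, glycolysis and hypoxia genes -0.13 and -0.06, nuclear oxidative phosphorylation genes -0.14 and -0.08, cytoskeleton and focal adhesion genes 0.16 and -0.07, and epithelial-mesenchymal genes 0.11 and -0.13. Histones had -0.19 and 0.77 over 7 genes, and small RNA silencing genes 0.11 and 0.03. Marker lists of fibroblasts (-0.36 and -0.57), leukocytes (0.42 and 0.10), endothelium (-0.28 and -0.10), squamous and alveolar epithelium (0.18 and 0.46) and embryonic kidney lines (0.02 and 0.01) had 3 to 6 measured genes each and did not stand apart with both.

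Globin transcripts lay farthest from the control among the named genes, and blood RNA in the shGFP library is a candidate explanation. Of 15 other red cell genes, 37.2% of 78 counts lay in shGFP (26.5 to 48.9), above its 24.4% of all counts, but this rested on ALAS2 (1, 1 and 13 counts in sh490, sh1362 and shGFP), without which the share was 25.4% (15.3 to 37.9). Of 15 white cell genes, 36.1% lay in shGFP (31.1 to 41.3), and without CORO1A, which the line itself expresses, 78.3% (65.8 to 87.9) from 3, 10 and 47 counts. HBB, the most abundant globin here, reached 638 CPM of the raw total in shGFP, S100A8 had 0, 0 and 5 counts, and AHSP and CA1 had 0 in each library. Reads passed from another library sequenced at the same time stay open and were not tested, and no biological explanation was tested.

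The sh1362 library stood apart, with a variance of its own deviation of 0.219 against 0.0375 for sh490 and 0.141 for shGFP. Simulated unchanged libraries gave 0.126 for sh1362 (0.120 to 0.137) and 0.126 for sh490 (0.119 to 0.132). The sh490 value thus lay below its simulated range as the sh1362 value lay above. The simulated spread was estimated from both hairpins together. Removing a GC trend left 100.5% of that variance and a length trend 99.2%, which argues against these trends as the cause. After thinning to equal depth the sh1362 variance was 5.21 times that of sh490, against 5.84 times before. The hairpin libraries were already close in depth, with 7791747 counts for sh490 and 7421552 for sh1362. Thinning could therefore hardly change their ratio, but depths this close argue against depth as the cause of the gap between these libraries. Counting error alone gave a simulated variance of 0.0122 for sh1362 (0.0113 to 0.0133), against the observed 0.219. Off-target silencing through the hairpin's seed may account for part: the word ATGGCAT in 3' untranslated regions went with lower values (t -17.0, 1523 genes), 3.17 times the strongest word on the higher side, and it lies in YES1 on chromosome 18 (GRCh38) in the coding sequence of exon 10, 736943 to 736949, and in the 3' untranslated region of exon 12, 722401 to 722407. For sh490 the ratio was 0.846, with ACTATAA lowest (t -11.6) and ATGGCAT, the sh1362 word, highest (t 13.7); each library was set against the mean of the others, so this comparison includes sh1362. Genes without the sh1362 words kept 86.2% of the variance, so carrying these words does not account for the whole difference. Similar words such as TGGCATT (t -10.7), and genes responding to a silenced gene, were not removed. Off-target silencing as the whole cause is therefore not excluded. Without the words the cholesterol median went from -0.59 to -0.37. The G2/M median stayed at -0.94, but only 1 of 38 searched members carried a word, so it could hardly change. A response to YES1 loss or a difference between cultures also stays open. YES1 itself was no lower with sh1362 (9.66% of shGFP) than with sh490 (6.79%), which gives no support to a deeper loss of YES1 in that library.

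Genes moving the same way with both hairpins may reflect chance differences of the shared shGFP library. The observed covariance of the folds was 1.0035 times the highest of the 100 simulated sets, and the counts of 94 and 69 genes lay inside the simulated ranges, but those of sh490 alone (162 and 165) lay below theirs and those of sh1362 alone (384 and 698) above, so the simulation does not match these libraries. A common response to YES1 silencing and chance in the lone control cannot be told apart. The simulated spread came from the hairpins themselves, which hold effects of their own, and this keeps the question open. Off-target silencing by the control hairpin, which would shift genes alike with both YES1 hairpins, was not tested separately. In the word search CAACGTT went with lower values in shGFP (t -5.81, largest absolute t of the permutations 5.09). The strongest word on the higher side was GGCATAT (t 9.64), a leading word of sh1362.

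In the YES1 coding sequence the first site of ATGGCAT lay 871 bases downstream of the first site of TACTATA, a leading word of sh490 that also occurs farther along. The numbers in the names of the hairpins differ by 872, but the labels do not say what the numbers mean. ACTATAA, the strongest word of sh490, has its only site in YES1 at base 2929 of the transcript, in the 3' untranslated region, and gives no such distance, and TACTATA was taken after the positions had been seen.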
